A study of Saccharomyces cerevisiae with 64 samples.

How the data were processed

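The series holds 64 libraries of budding yeast, Saccharomyces cerevisiae: 58 of genomic DNA and 6 of polyadenylated RNA. The 29 groups were taken from the strain, drug, time and antibody labels. The DNA assay was quantitative BrdU immunoprecipitation, in which newly made DNA is marked with the thymidine analogue bromodeoxyuridine (BrdU) and pulled down with an antibody. Per the labels' protocols, DNA sheared to about 300 bp was ligated to barcoded adapters, equal amounts of several barcoded samples were pooled, 20 ng was kept as Input and 1 µg of the pool was immunoprecipitated. Samples of a pool compete for the same antibody, so that signal relative to Input compares in amount between them. Whether the deposited columns were scaled by Input is not given in the sources used here, and their folds are therefore not known to be ratios of amounts.

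Per the labels' protocols, cells were blocked in G1 with 7.5 nM α-factor for 3 h at 25 °C, kept in 2% galactose for 2 h, which induced the genes on galactose promoters (RNR3 stood under another promoter), and released into S phase. In the experiments with hydroxyurea (HU), cells were released for 60 min in 0.2 M HU, an inhibitor of ribonucleotide reductase that stops forks near early origins, with 400 µg/mL BrdU. In the time course, cells without drug received 800 µg/mL BrdU in pulses of 20 to 35, 30 to 45 and 40 to 55 min after release.

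The deposited BrdU signal was given by the authors in 4 tables with 13 columns, 1 value for each 50 bp bin, never negative. Each column combined the libraries of a group, which was seen in the column names; how they were combined, smoothed and scaled is not given in the sources used here. In 3 of the 4 tables the highest bin of the control column was exactly 1, so the values are relative units. Per the submitters' processing notes, Bowtie2, SAMtools and bedtools and the yeast genome build R64 were used. The table of the double mutant had a longer chromosome III and chromosome V than the other 3 tables, so its coordinates on these chromosomes beyond the altered sites are not those of R64. Origins beyond these sites were measured there at an offset equal to the difference in length, to the nearest bin (10150 bp on chromosome III), and origins inside the altered stretches were left out. On chromosome III, 12 of 12 segments of 20 kb beyond the site had a higher rank correlation with the HU table at this offset than without it, and the segment around ARS315 had 0.958 at the offset and -0.31 without. Columns for single libraries and for Input were not used here, so depth per library is unknown, and no standard deviation, n or test could be given for any BrdU value. The number of per-sample columns that matched no sample was 0.

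The deposited RNA table held the authors' FPKM for each gene and group, with p-values and q-values of the 3 pairwise comparisons; its columns are those of Cuffdiff per the file headers, and TopHat2 and Cufflinks are named in the submitters' processing notes. Each group had 2 libraries per the labels. Whether these came from separate cultures is not stated, so the p-values may measure technical spread only. Folds were recomputed from the FPKM because the deposited column of log2 folds was damaged in part, and no fold was given where a group was listed at 0. Of 7053 gene names in 6931 entries of the table, 6101 matched the R64 gene table, and 106 entries held several overlapping genes that the authors' counting did not separate.

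The design fixed before the data were examined, with its gene lists, origin classes, named-gene rule, windows and most alternatives, assumed counts per library and quasi-likelihood tests. The files held combined signal instead. BrdU values were therefore compared without a test, and an origin was called higher or lower when its signal differed by at least 2-fold, a size rule chosen after seeing that no test was possible. The RNA calls are those of the authors at q below 0.05.

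Origins were called as peaks without group labels, since the design had a fallback for a reference without origins: the mean of the 3 HU columns was smoothed by a 1 kb running mean, and local maxima at least 3 times the genome median and at least 5 kb apart were kept. This mean includes the overexpression columns, so origins seen only with overexpression are among the peaks, and the choice favours rises. As alternatives, origins were restricted to those with at least 1.5 or 3 times background in the HU no OE column, with the same terciles, or called in the no OE column of the time course to 35 min, with terciles formed anew from the RNR3 control column; both were chosen after seeing the data. Of 325 peaks, 2 lay in the ribosomal DNA array (chromosome XII 451786 to 489469) and were left out, and 318 reached 1.5 times background and were used. Background was the median of 2 kb windows further than 10 kb from any peak. Sites that were called because they rose with OE, and their surroundings, are thus left out of it, which by construction lowers its share of rises. In the later pulses of the time course, background windows held signal from between origins, so background there is not an absence of signal. The signal of an origin is its mean over a 2 kb window, for which at least 50% of the bins had to hold a value. Origins were named by position and nearest gene. ARS names were added from published positions within 1.5 kb. Bins at 0 in every column of a table were treated as missing.

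Origin classes were centromere-proximal (within 20 kb of a centromere), telomere-proximal (within 30 kb of a chromosome end), and the early and late tercile by signal in the no OE column of the RNR3 table (for the RNR3 table itself, of the HU table). These terciles rank signal in HU, so late, weak and inactive sites are not separated in the late tercile. The RNR3 control column had low contrast, with a median origin window of 0.173 beside a background of 0.156. For the centromere and telomere classes, the percentile of the class median among 10000 random lists matched on mean signal describes these columns and is not a test. The class of origins with forkhead motifs needed a genome sequence and was not analysed here. The width of origin signal was measured over 159 isolated origins with no other within 20 kb, as the signal 3 to 6 kb away relative to that within 1 kb. Shared controls were simulated with 1000 draws for origins and 200 for RNA, as columns of independent, equal noise without effect.

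The 20 gene lists, all but the subtelomeric one written out gene by gene, were forkhead factors and partners, the CLB2 cluster, G1/S genes of SBF and MBF, histones, replication initiation, dNTP supply, DNA damage-induced genes, pheromone response, α-cell genes, galactose genes, stress genes of Msn2 and Msn4, ribosome biogenesis, ribosomal proteins without a close paralog, methionine, phosphate, iron, flocculation, mitochondrially encoded genes, subtelomeric genes within 20 kb of a chromosome end, and 1 list that, like single genes of others, is not reported here. Members past q of 0.05 were counted per direction. Fisher's exact test (1-sided, against the other tested genes, with Benjamini-Hochberg adjustment over lists and directions within a comparison) was added after seeing the data, because a test on single libraries was not possible. It treats genes as independent, which members of a list need not be, so its p-values do not measure spread between libraries or cultures.

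Named items followed 1 rule. For RNA these were FKH1, FKH2, the 10 largest rises and 10 largest falls past q in the comparisons with no OE, and up to 4 members with the smallest q of each list with a call. For BrdU these were ARS305, ARS501, ARS607, ARS603, ARS416 and ARS315, and the 5 largest rises and 5 largest falls past 2-fold. The rule also asked that single libraries of the groups do not overlap, which could not be applied.

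The peak caller and the size rule were tested on simulated data: 144 of 144 planted peaks were found with 0 false ones, and 49 of 49 planted 3-fold rises but 0 of 95 unchanged or 1.3-fold ones passed 2-fold. The adjustment step recovered 200 of 200 changed genes among 6000, with 9 unchanged genes past q. Of 200 random lists without effect, 11 had a percentile in either extreme tail. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives were windows of 1 and 5 kb, scaling to the IP total or to mitochondrial DNA, background subtraction, higher peak minimums, leaving out chromosome ends and URA3, a 1.5-fold rule, other flanks, q below 0.01 and a 2-fold minimum for RNA.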

Results

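Replication of the yeast genome was measured in cells that overexpressed (OE) the forkhead transcription factors Fkh1 or Fkh2 from a galactose-inducible promoter, and in control cells with the empty promoter (no OE). The labels describe 5 kinds of data: BrdU incorporation in HU for no OE, Fkh1 OE and Fkh2 OE (3 IP and 3 Input libraries each), a time course without drug for no OE and Fkh1 OE (2 and 2 per pulse), HU in a double mutant lacking FKH1 and FKH2 whose late origin ARS501 was replaced by the early origin ARS305, with and without Fkh1 OE (2 and 2 each), HU in cells that overexpressed RNR3, a subunit of ribonucleotide reductase, and their controls (2 and 2 each), and RNA of G1-arrested cells (2 per group). Every BrdU value below is the authors' combined value of a group in relative units. Differences between BrdU columns therefore have no replicate check, and depth is unknown. Whether the columns of a table are on 1 scale of amount is not given in the sources used here, so folds and totals are those of the deposited values. "Rose" and "fell" are used for origins only from 2-fold on, and for genes only where the authors' q was below 0.05.

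The targeted genes were examined first. In the authors' deposited table, FKH1 RNA was 1458 FPKM in Fkh1 OE and 20.9 in no OE, 69.6-fold higher (q = 0.000327). In the authors' deposited table, FKH2 RNA was 2220 FPKM in Fkh2 OE and 14.3 in no OE, 155-fold higher (q = 0.000327). In the BrdU table of the double mutant, signal inside FKH1 (chromosome IX 100781 to 102235) was 0 without and 0.00576 with Fkh1 OE. All 46 bins inside FKH2 (XIV 495701 to 498289) were listed at 0 in both columns of that table and 0 of 46 in every column of the other 3 tables. Such bins, 4.91% of the double mutant's table, were treated as missing, a rule that by itself does not separate a deletion from a missing value. At FKH2, the 0 of 46 bins so listed in the other tables argue against a stretch that cannot be mapped. The length of chromosome XIV also differed by 0 bp between the tables. The deletion named in the labels would give these values. BAR1 (IX 322342 to 324105), which encodes the protease that degrades α-factor, held no bin above 0 in any table and was missing by the same rule.

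The comparison in HU asked which origins incorporated more BrdU in early S phase when Fkh1 was overexpressed. Signal rose at 153 of 318 origins and fell at 5, and the median origin was 1.94-fold higher. Of 3192 background windows, 4.82% were past 2-fold up, a share kept low in part because peaks called with the OE columns were left out of them. The rise was larger in the late tercile, which had the lowest signal in the RNR3 control column. Its median rose from 0.00760 to 0.0345, and its median fold was 5.53, with 73 of 105 origins past 2-fold up and 1 past 2-fold down. In the early tercile the median went from 0.360 to 0.557, with a median fold of 1.23, 18 of 106 past 2-fold up and 3 down. Terciles by the time course control to 35 min gave median folds of 5.65 (late, 74 of 105 higher) and 1.23 (early, 18 of 106 higher). Origins were called on a mean that includes the OE columns, which favours sites that rose, and the size of the late rise depended on it in checks chosen after seeing the data. Late origins of at least 1.5 times background in no OE had a median fold of 2.00 (31 of 63 higher), and those of at least 3 times 1.36 (10 of 30 higher, and 65 of all 206), choices that in turn favour falls. Over origins called in the no OE column of the time course to 35 min, a separate set of libraries, 79 of 223 were higher, and the late tercile had a median fold of 1.65 (36 of 73 higher) and the early tercile 1.16 (6 of 76 higher). The early origins ARS305 (chromosome III 38601 to 40600, between genes), ARS315 (III 223851 to 225850) and ARS416, also called ARS1 (IV 461601 to 463600, beside TRP1), stood at 1.32, 1.40 and 1.45 times their control signal, and ARS607 (VI 198201 to 200200) at 1.04 times.

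The 5 largest rises were at sites near background in control cells. Signal inside CHS1, a chitin synthase gene (XIV 278851 to 280850), rose from 0.00485 to 0.184, 38.0-fold. Beside RAD30, which encodes DNA polymerase eta (IV 1301701 to 1303700), it rose from 0.00384 to 0.140, 36.4-fold. The origins beside YPT11, encoding a Rab GTPase of organelle inheritance (XIV 60601 to 62600), YOR296W (XV 873151 to 875150) and VAM6, a vacuolar fusion gene (IV 315851 to 317850), rose 33.3-fold, 26.7-fold and 23.3-fold. All 5 falls were at chromosome ends or at URA3. The end of chromosome V near YEL077C (1 to 1150) fell from 0.205 to 0.0462, 4.43-fold. URA3, the uracil biosynthesis gene (V 115501 to 117500), fell 2.97-fold. The ends of chromosome VIII inside YHL050C (1 to 1650), chromosome XII near YLL067C (1 to 1000) and chromosome II near YBL113C (1 to 1000) fell 2.81-fold, 2.63-fold and 2.49-fold. Reads at these ends and at URA3 can be shared with other copies, near-identical subtelomeres in the first case and plasmids in the second. The late origins ARS501 (V 548001 to 550000) and ARS603 (VI 68001 to 70000) were below the peak threshold. ARS501 had 0.970 times background in no OE and 2.70 times in Fkh1 OE, and ARS603 had 1.31 and 3.08 times.

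Origins near centromeres, which replicate early in yeast, differed little: their median was 1.24-fold higher over 45 origins, at percentile 8.27 of random lists matched on signal. The 25 telomere-proximal origins had a median fold of 1.05, with 4 past 2-fold up and 3 down, whereas matched random lists had a median log2 fold of 1.63 and none of the 10000 lay as low (percentile 0). Total nuclear signal was 1.39 times that of the control, background windows 1.36 times and mitochondrial DNA 1.19 times. Scaling to the total removed this gain, lowered the median log2 fold from 0.95 to 0.48, and gave 132 origins higher and 9 lower. The early, centromere and telomere classes then turned to 0.884, 0.889 and 0.757. Under that scaling the direction turned at ARS305 (0.951 times control) and ARS607 (0.748 times), while ARS315 and ARS416 stood at 1.01 and 1.04 times.

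**Figure D1:**
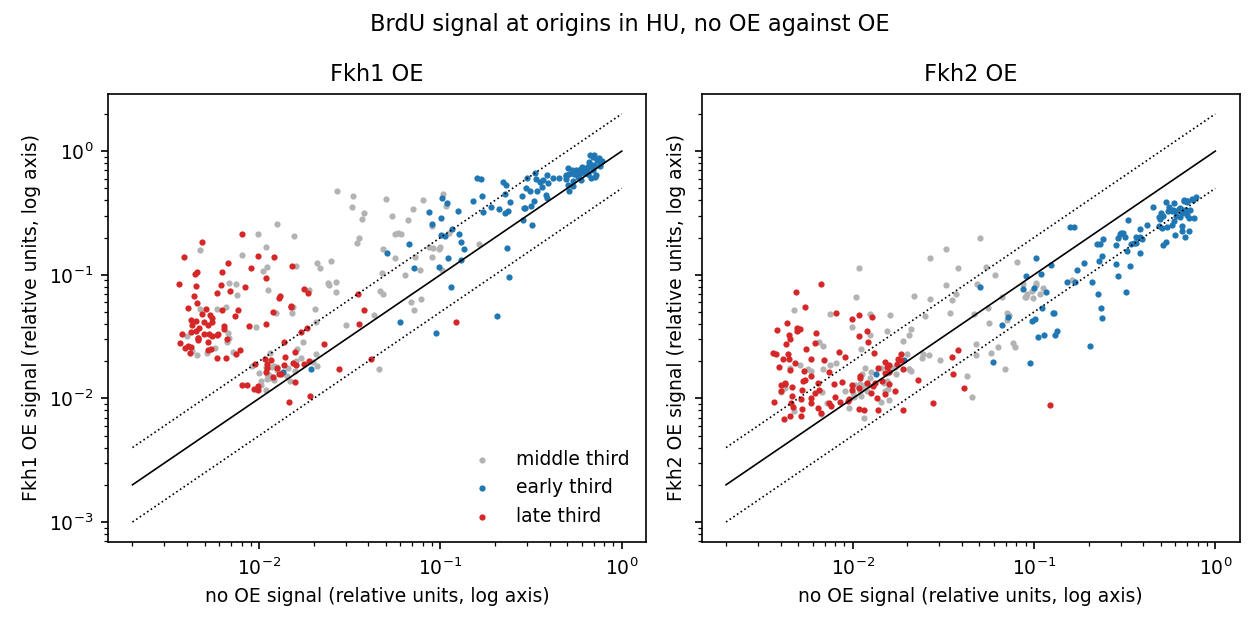
BrdU signal of each of 318 origins in HU (relative units, log axes), with no OE on the horizontal axis and Fkh1 OE (left) or Fkh2 OE (right) on the vertical axis; the solid line marks equal signal, the dotted lines 2-fold, and colours the early, middle and late class of the origin in the RNR3 control column. Late origins lie above the upper dotted line with Fkh1 OE, 73 of 105 of them, and 44 of 106 early origins lie below the lower dotted line with Fkh2 OE.

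With Fkh2 OE in HU, early origins were lower than in the same control, and the late tercile was higher under the main origin call. Signal rose at 77 of 318 origins and fell at 57, with a median fold of 0.972. In the late tercile, 48 of 105 origins rose and 5 fell (median fold 1.78, from 0.00760 to 0.0145), while in the early tercile 44 of 106 fell and 0 rose (median fold 0.540, from 0.360 to 0.202). The rises depended on how origins were called, with 37 of 268, 13 of 206 and 25 of 223 in the same 3 checks. The late tercile's median fold was 1.16 (15 higher and 5 lower of 63) and 0.929 (1 higher and 5 lower of 30) where no OE had at least 1.5 and 3 times background, and 1.08 (16 higher and 2 lower of 73) over origins called in the time course control, where the early tercile had 0.497. The early origins ARS305, ARS315, ARS416 and ARS607 had 0.562, 0.587, 0.626 and 0.534 times the control signal.

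CHS1 again had the largest rise, from 0.00485 to 0.0730, 15.1-fold. It was followed by the origins beside SOL1 (XIV 690751 to 692750), YPT11, MTC2 (XI 257051 to 259050) and USV1, a transcription factor gene (XVI 115601 to 117600), which rose 12.5-fold, 11.0-fold, 10.4-fold and 10.1-fold. URA3 fell 14.0-fold, from 0.123 to 0.00879. The chromosome ends at YEL077C, YBL113C, YHL050C and YLL067C fell 7.67-fold, 5.33-fold, 4.94-fold and 4.46-fold. Of the late origins named in advance, ARS501 stayed at background (0.988 times) and ARS603 had 1.74 times background. Centromere-proximal origins had a median fold of 0.603 (0 up and 4 down of 45, percentile 90.2), and telomere-proximal origins 1.06 (2 up and 7 down of 25, percentile 22.9).

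Total nuclear signal was 0.649 times control while background windows were at 1.05 times and mitochondrial DNA at 1.03 times. The split of calls depended on the scaling and the windows: scaled to the total, 111 origins were higher and 16 lower, 87.4% higher in place of 57.5%, and the median log2 fold moved from -0.04 to 0.57. Windows of 5 kb gave 54 higher and 75 lower, and peaks of at least 10 times background 23 higher and 49 lower. The median over all origins was thus on either side of 1, and the early tercile was below 1 under both scalings (0.828 after scaling to the total). The late, centromere and telomere classes were then at 2.73, 0.924 and 1.63.

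Set directly against Fkh1 OE, Fkh2 OE had lower signal at most origins: 208 of 318 were lower by at least 2-fold and 0 higher, and the median fold was 0.408. Both terciles were lower by a similar factor, 0.407 in the early tercile (88 of 106 lower) and 0.414 in the late tercile (59 of 105 lower). The largest falls were inside ICP55, a mitochondrial peptidase gene (V 315901 to 317900, 9.51-fold), inside ELP3, the catalytic subunit of Elongator (XVI 383801 to 385800, 7.83-fold), beside ARV1, a sterol transport gene (XII 621851 to 623850, 7.54-fold), inside UBP12, a ubiquitin protease gene (X 66501 to 68500, 7.47-fold), and inside MAL33, a maltose activator gene (II 800801 to 802800, 7.26-fold). ARS305, ARS315 and ARS416 fell 2.36-fold, 2.39-fold and 2.32-fold, and ARS607 was at 0.512 times. Centromere-proximal origins were at 0.482 (0 up and 26 down) and telomere-proximal origins at 0.803 (0 up and 6 down), both at percentile 99.995 of matched lists, that is, less reduced than other origins of their signal. Scaling to the total left 15 higher and 38 lower (28.3% higher) and a median log2 fold of -0.20 in place of -1.29. The early and late terciles were then at 0.868 and 0.883, and the centromere and telomere classes turned to 1.03 and 1.71.

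Origins that responded to the 2 factors overlapped. Across 318 origins, log2 folds of Fkh1 OE and Fkh2 OE had a Pearson r of 0.868 and a Spearman rho of 0.826, and all 77 origins higher with Fkh2 OE were also higher with Fkh1 OE, where independent sets would share 37.0. Both comparisons use the same control column, which by itself gave an r of 0.502 in simulated columns without effect (0.410 to 0.577). The simulated columns had independent, equal noise. A noisier control would give a higher r, and the noise of the control column is not known. The covariance was 1.57. The controls could not be split, so how much of the excess comes from the shared column is not known. Origins are not independent replicates.

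The time course asked when in an unperturbed S phase the difference between Fkh1 OE and no OE arose. In the pulse of 20 to 35 min, signal rose at 175 of 316 origins and fell at 0, with a median fold of 2.18. Of 3180 background windows, 53.1% were past 2-fold up as well. The late tercile went from 0.0197 to 0.114 (median fold 4.71, 82 of 104 higher) and the early tercile from 0.321 to 0.517 (median fold 1.49, 16 of 106 higher). Where the HU control had at least 1.5 and 3 times background, the late tercile had a median fold of 2.56 (40 of 62 higher) and 1.96 (13 of 29 higher), and 76 of 204 origins were higher in the latter case. ARS501 had 0.0110 in no OE and 0.0669 in Fkh1 OE (1.65 and 5.34 times background), and ARS603 had 0.00616 and 0.0673 (0.924 and 5.38 times). ARS305, ARS315, ARS416 and ARS607 were at 1.33, 1.86, 1.85 and 1.23 times control. The largest rises were inside HKR1, an osmosensor gene (IV 1306851 to 1308850, 25.5-fold), and beside SEI1, a lipid droplet gene encoding seipin (XII 927201 to 929200, 18.3-fold), COS9, a subtelomeric gene (XI 14951 to 16950, 16.6-fold), TEX1, an mRNA export gene (XIV 168851 to 170850, 15.9-fold), and SAP4 (VII 63401 to 65400, 15.1-fold). Centromere-proximal origins had a median fold of 1.64 (percentile 58.1), and the 24 telomere-proximal origins 1.14 (6 higher, percentile 0).

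In the pulse of 30 to 45 min, 66 of 316 origins were higher and 0 lower, and the median fold was 1.21. A larger share of background windows, 57.5% of 3186, was past 2-fold up, and their median was 2.60 times control. The late tercile was at 0.142 in no OE and 0.274 in Fkh1 OE (median fold 1.82, 47 of 104 higher; 1.18 and 4 of 29 where the HU control had at least 3 times background, with 8 of all 204), while the early tercile had a median fold of 1.01 with 0 calls. The largest rises were at COS9 (5.63-fold), beside IWR1, a nuclear import gene (IV 252901 to 254900, 4.42-fold), inside DAN4, a cell wall mannoprotein gene (X 714051 to 716050, 4.13-fold), inside HKR1 (4.12-fold) and beside MGL2 (XIII 687901 to 689900, 4.06-fold). ARS501 had 0.107 in no OE and 0.213 in Fkh1 OE, but relative to background it was lower, 3.32 and 2.54 times. ARS603 had 0.0583 and 0.204, which was 1.80 and 2.43 times background. ARS305, ARS315, ARS416 and ARS607 were at 0.907, 0.918, 0.906 and 1.01 times control. Centromere-proximal origins were at 1.03 (percentile 28.5) and telomere-proximal origins at 0.872 (4 higher, percentile 0).

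In the pulse of 40 to 55 min, 6 of 316 origins were higher, 0 were lower and 274 lay below their control, with a median fold of 0.795 (turning to 1.01 after scaling to mitochondrial DNA), while 15.8% of 3200 background windows were past 2-fold up. Both terciles were below 1, at 0.755 (early) and 0.842 (late). The 5 largest rises were at the end of chromosome III near GEX1 (1 to 1200, 2.66-fold), inside TAF7, a TFIID subunit gene (XIII 722101 to 724100, 2.38-fold), inside PXR1, a nucleolar gene (VII 1050251 to 1052250, 2.28-fold), and at the ends of chromosomes XI near PAU16 (1 to 1000, 2.20-fold) and XV near YOL166W-A (1 to 1000, 2.15-fold). All 5 were below background in no OE (0.324 to 0.859 times), and GEX1 (0.939 times), TAF7 (0.633 times) and PXR1 (0.958 times) stayed below it with Fkh1 OE. ARS305, ARS315, ARS416 and ARS607 were at 0.808, 0.769, 0.714 and 0.794 times control, and ARS501 had 0.263 and 0.228 (1.33 and 0.942 times background). Centromere-proximal origins had a median fold of 0.765 (percentile 3.03) and telomere-proximal origins 0.922 (3 higher, percentile 99.85). In this pulse 0 origin windows of either column reached 5 times background. Background itself stood at 0.198 in no OE and 0.242 in Fkh1 OE, beside 0.00666 and 0.0125 in the pulse to 35 min. It thus held signal from between origins, and a value below it does not mean absent signal.

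Compared within origins, the effect of Fkh1 OE was smaller at 55 than at 35 min by at least 2-fold at 226 of 316 origins and larger at 3, with a median difference of -1.47 in log2 fold. Scaled to the total, it was smaller at 99 and larger at 18, with a median difference of -0.41. Total nuclear signal in Fkh1 OE was 2.13, 1.36 and 1.02 times control in the 3 pulses (0.838 over origin windows in the last), and background windows were at 1.88, 2.60 and 1.22 times, so signal between origins was higher too. Scaled to the total, the first pulse gave 84 higher and 15 lower (84.8% higher in place of 100%) with a median log2 fold of 0.04 in place of 1.13, and ARS305, ARS315, ARS416 and ARS607 turned to 0.628, 0.877, 0.872 and 0.579 times control, as did the early (0.702), centromere (0.772) and telomere classes (0.537), while the late tercile stood at 2.22. The second pulse then gave 25 higher and 4 lower (86.2% higher in place of 100%), with the median log2 fold at -0.17 in place of 0.28, and the early and centromere classes turned to 0.743 and 0.759. Background subtraction left 135 measurable origins in the last pulse, with 3 higher and 106 lower and 118 with a smaller effect than at 35 min. The background taken away in that pulse held signal from between origins. A 1.5-fold rule gave 10 higher and 16 lower there.

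**Figure D2:**
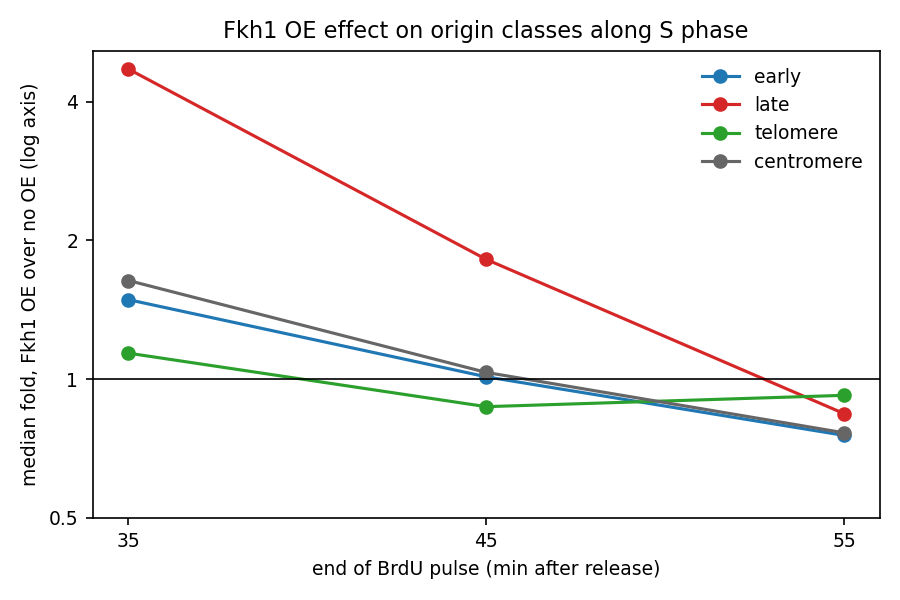
Median fold of Fkh1 OE over no OE (log axis) for early, late, telomere-proximal and centromere-proximal origins against the end of the BrdU pulse in minutes after release; each point is the median of a class, without error since each group has 1 combined column. The late class falls from 4.71 at 35 min to 1.82 and 0.842.

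The HU and time course experiments used separate libraries. Log2 folds of Fkh1 OE in HU and in the first pulse had r = 0.874 and rho = 0.891 over 316 origins, and 148 origins were higher in both, where independent sets would share 84.7. For the second pulse r was 0.603 and rho 0.689, and for the third -0.12 and -0.08. Fkh2 OE in HU and Fkh1 OE in the first pulse had r = 0.820 and rho = 0.813.

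The double mutant asked what Fkh1 OE does at origins in cells without either chromosomal forkhead gene, and whether ARS305 keeps its early firing at the late ARS501 site. Signal rose at 75 of 313 origins and fell at 101, with a median fold of 0.755. Of 3167 background windows, 17.4% were past 2-fold down. Origins were called in cells with both forkhead genes, so sites active mainly in the double mutant can be missed and count as background. This limits the counts, medians and correlations given for the double mutant. Many origins of the early tercile rose and many of the late tercile fell: the early tercile went from 0.147 to 0.347 (median fold 1.78, 50 of 105 higher and 9 lower) and the late tercile from 0.0477 to 0.0174 (median fold 0.461, 7 of 104 higher and 53 lower). ARS607 rose 5.05-fold, from 0.103 to 0.518, ARS315 (234001 to 236000 in that table's coordinates) was at 1.95 times and ARS416 at 0.658 times the double mutant's signal. ARS603 fell from 0.0205 to 0.00845.

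The largest rises were inside TOR2, a growth-control kinase gene (XI 54951 to 56950), from 0.0124 to 0.419 (33.8-fold), at the ends of chromosomes II near YBL113C (25.9-fold) and VIII inside YHL050C (18.2-fold), beside HXT6, a hexose transporter gene whose near-identical copy HXT7 can share its reads (IV 1158251 to 1160250, 17.4-fold), and inside YML119W (XIII 30501 to 32500, 15.8-fold). The largest falls were beside RAD53, the checkpoint kinase gene (XVI 260501 to 262500), from 0.237 to 0.00779 (30.4-fold), PUP2, a proteasome subunit gene (VII 998501 to 1000500, 24.2-fold), TKL1, encoding transketolase (XVI 694101 to 696100, 23.8-fold), RPC19, a subunit of RNA polymerases I and III (XIV 411401 to 413400, 23.0-fold), and USV1 (22.6-fold). USV1 had risen 10.1-fold with Fkh2 OE in HU. Centromere-proximal origins had a median fold of 0.604 (0 higher and 14 lower of 45, percentile 0) and the 22 telomere-proximal origins 1.57 (10 higher and 1 lower, percentile 99.97).

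At the swapped site on chromosome V the peak lay at 549875 in the coordinates of that table. Signal in the 2 kb around it was 0.0340 in the double mutant and 0.429 with Fkh1 OE, 12.6-fold higher. Because inserted sequence could share reads with a native copy, if one remained, the flanks 1 to 3 kb away were measured, and these rose from 0.0163 to 0.0806, 4.93-fold. Flanks 3 to 6 kb away rose 2.22-fold. On chromosome III of that table, the highest 2 kb window between 35001 and 61000, the stretch around the native ARS305, had 0.0153 without and 0.00924 with Fkh1 OE. These were 2.39 and 1.80 times background, so no strong peak was seen at the native place. The chromosome is altered there in that table, so an absent and an inactive native copy cannot be told apart. Beside that stretch, at 29001 to 31000, signal was 25.3 times background without and 16.9 times with Fkh1 OE, and 2.81 times in the HU control.

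Total nuclear signal was 0.656 times that of the double mutant. Scaled to the total, 104 origins were higher and 73 lower (58.8% higher in place of 42.6%), and the median log2 fold moved from -0.41 to 0.19. The early, late, centromere and telomere classes were then at 2.69, 0.696, 0.912 and 2.38. Windows of 5 kb gave 58 higher and 123 lower (32.0% higher), and peaks of at least 10 times background 64 higher and 31 lower (67.4% higher), with the median fold turning to 1.44. Across 313 origins the log2 folds went opposite to those of Fkh1 OE in HU (r = -0.39, rho = -0.41), with 29 origins higher in both where independent sets would share 36.7, and opposite to those of Fkh2 OE (r = -0.57, rho = -0.55).

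**Figure D3:**
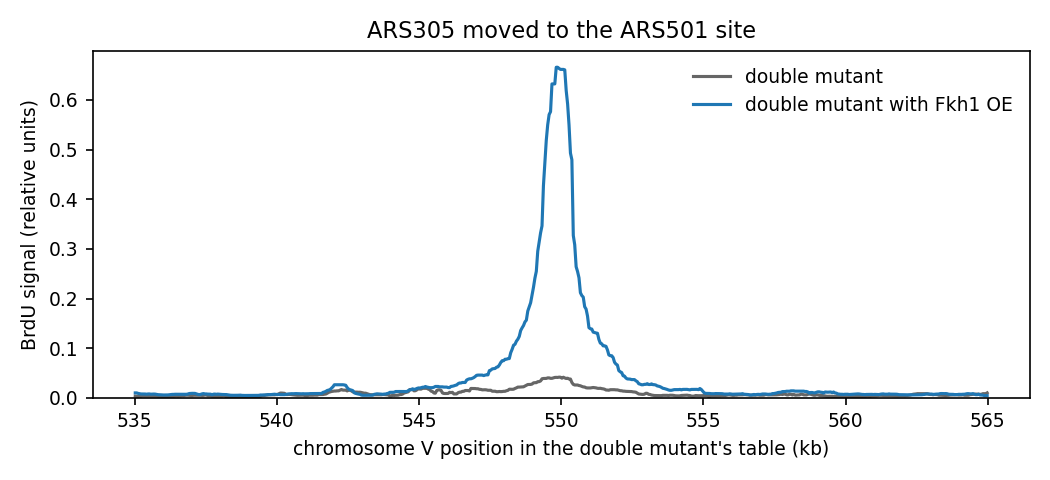
BrdU signal in HU (relative units) along chromosome V around the ARS305 copy at the ARS501 site, position in kb in the double mutant's own coordinates, without (grey) and with (blue) Fkh1 OE; each line is the authors' combined column. The 2 kb around the peak average 0.0340 without and 0.429 with Fkh1 OE.

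The RNR3 comparison asked whether more ribonucleotide reductase changes origin signal in HU. Signal rose at 13 of 317 origins and fell at 0, with a median fold of 1.32. The median log2 fold was 0.59 in the early tercile (0.381 to 0.577) and 0.10 in the late tercile (0.161 to 0.168, turning to 0.928-fold after scaling to the total). In each, 1 origin was past 2-fold. The late tercile lay near background, 0.156 in no OE and 0.143 in RNR3 OE, which by itself holds its fold near 1. The gap between early and late origins can therefore come from background. After background subtraction, the median over 311 origins was 3.10-fold. The largest rises were beside YBL111C near the end of chromosome II (4751 to 6750, 4.21-fold), inside MDM38, a mitochondrial gene (XV 271301 to 273300, 3.04-fold), inside DAL1, encoding allantoinase (IX 405751 to 407750, 2.84-fold), inside ASF1, a histone chaperone gene (X 195851 to 197850, 2.70-fold), and beside ADY4, a spore formation gene (XII 591601 to 593600, 2.57-fold). ARS305, ARS315, ARS416 and ARS607 were at 1.29, 1.08, 1.57 and 1.22 times control. ARS501 had 0.143 and 0.133, and ARS603 0.175 and 0.162. Centromere-proximal origins had a median fold of 1.47 (3 higher, percentile 37.5) and telomere-proximal origins 1.12 (2 higher, percentile 1; 0.969 after scaling to the total).

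The control column of this table had a high background, 0.156, and 1 origin window at 5 times background or more, so contrast was low. The count of rises depended on the setting: it was 208, with 8 falls, after background subtraction, 47 in 5 kb windows, 35 after scaling to mitochondrial DNA, 6 after scaling to the total (which moved the median log2 fold from 0.40 to 0.19), and 109 with a 1.5-fold rule. Log2 folds had r = -0.24 and rho = -0.21 with those of Fkh1 OE in HU over 317 origins, which are not independent replicates.

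The spread of signal around origins was measured at 159 isolated origins. In HU, signal 3 to 6 kb away was 19.4% of that at the origin in no OE, 9.19% in Fkh1 OE and 14.5% in Fkh2 OE. Late origins had a median of 0.00760 in no OE beside a background of 0.00413. A rise at such origins alone lowers this share, so the share does not show how far forks moved. In the double mutant it was 21.8%, and 16.3% with Fkh1 OE. In the RNR3 table it was 73.9% in no OE and 72.8% in RNR3 OE, and the direction depended on the background: after its subtraction the values were 26.8% and 38.1%. Over origins of at least 10 times background (3 times in the RNR3 table), a restriction chosen after seeing the data, they were 31.0% and 71.2% over 13 origins in the RNR3 table, 4.40%, 3.47% and 5.10% in no OE, Fkh1 OE and Fkh2 OE over 47 origins, and 14.0% without and 6.04% with Fkh1 OE in the double mutant over 50 origins. After background subtraction the values in HU were 7.12% in no OE, 2.56% in Fkh1 OE and 3.09% in Fkh2 OE.

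RNA of G1-arrested cells was compared to see which transcripts differed before replication began. With Fkh1 OE, 347 genes were higher and 335 lower of 6212 tested in the authors' deposited table, and 24 and 59 of these by at least 2-fold. Genes of ribosome biogenesis and of iron uptake were called higher more often than other genes. Members of a list can change together, so the Fisher p-values given for lists do not measure spread between cultures. In the authors' deposited table, 16 of 24 ribosome biogenesis genes were higher and 0 lower (Fisher's exact test, adjusted p = 1.26e-13; 18 adjusted over the list alone), among them RPA135, a subunit of RNA polymerase I (2.12-fold), UTP4 (2.08-fold), SSF1 (1.92-fold) and ERB1 (1.86-fold). Of 12 iron uptake genes, 4 were higher in the authors' deposited table (adjusted p = 0.0441 by Fisher's exact test; 5 adjusted over the list alone): FET3 (2.59-fold), SIT1 (2.10-fold), FTR1 (1.75-fold) and ARN1 (1.52-fold).

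The largest rises with Fkh1 OE after FKH1, in the authors' deposited table, were an entry that joins APC4 with YDR118W-A (6.18-fold, overlapping genes that cannot be separated), the chitinase gene CTS1 (4.36-fold, 93.4 to 407 FPKM), the cell wall glucanase gene SCW11 (4.22-fold), YKL102C (3.36-fold, q = 0.0417), MFA2, an a-factor gene (2.83-fold), RPL41A (2.62-fold, a gene with a near-identical copy and so uncertain), DSE2 (2.60-fold), FET3 and JJJ3 (2.55-fold). The largest falls in the authors' deposited table were CSN9 (3.78-fold), PDS1, encoding securin (3.51-fold, 17.4 to 4.97 FPKM), YKL069W (3.19-fold), the kinetochore gene MTW1 (2.93-fold), IPL1, encoding the Aurora kinase (2.92-fold), ERS1 (2.91-fold), MDJ2 (2.85-fold), the spindle genes SHE1 (2.84-fold) and FIN1 (2.82-fold), and CLB4, a mitotic cyclin gene (2.77-fold).

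The other lists reported here did not pass the adjusted Fisher test with Fkh1 OE. Stress genes of Msn2 and Msn4 had 4 lower and 0 higher of 19 in the authors' deposited table (4 lower adjusted over the list alone), with TSL1 (2.28-fold lower), SOL4 (1.85-fold), HSP26 (1.84-fold) and ALD3 (1.61-fold). The pheromone list had 3 higher and 0 lower of 22 in the authors' deposited table (3 adjusted over the list alone), with MFA2, MFA1 (2.55-fold) and STE6 (1.51-fold). Histones had 2 higher and 1 lower of 9 in the authors' deposited table (2 and 1 adjusted over the list alone), HTA2 (1.82-fold), HHF1 (1.63-fold) and the linker histone gene HHO1 (2.35-fold lower). Of 9 forkhead factors and partners, FKH1 was higher and NDD1, a co-activator of Fkh2, lower (1.62-fold) in the authors' deposited table (1 and 1 adjusted over the list alone). The α-cell list had 2 higher of 4 in the authors' deposited table (2 adjusted over the list alone), SAG1 (1.78-fold) and MF(ALPHA)1, listed at 0 in no OE. Phosphate genes had PHO84 higher (1.71-fold) of 13 in the authors' deposited table (1 adjusted over the list alone), and G1/S genes had SMC3 higher (by 0.59 in log2 fold) and SWE1 lower (1.67-fold) of 34 (0 and 1 adjusted over the list alone).

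Single calls that were lost when adjusted over the list alone (0 left in each) were, in the authors' deposited table, CHS2 higher (1.51-fold) of 24 genes in the CLB2 cluster, SLD2 lower (1.67-fold) of 27 replication initiation genes, SML1 higher (1.44-fold) of 11 dNTP supply genes, and RAD54 lower (1.47-fold) of 13 damage-induced genes. Likewise lost were, in the authors' deposited table, RPS13 higher (1.45-fold) of 16 ribosomal protein genes and MUP1 higher (1.51-fold) of 17 methionine genes. Of 179 subtelomeric genes, 4 were higher and 3 lower in the authors' deposited table (0 and 0 adjusted over the list alone), among them YMR317W (27.2 to 18.1 FPKM), YPL277C (1.47-fold lower), MSC1 (1.45-fold lower) and an entry joining YIL174W with YIL175W that was listed at 0 in no OE. No call was made among 9 galactose genes, 4 flocculation genes and 7 mitochondrially encoded genes in the authors' deposited table (0 adjusted over the list alone).

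With Fkh2 OE, 850 genes were higher and 1058 lower of 6208 tested in the authors' deposited table, and 222 and 438 of these by at least 2-fold. Ribosome biogenesis genes were again called higher more often than other genes, with 21 of 24 genes higher and 0 lower in the authors' deposited table (Fisher's exact test, adjusted p = 3.18e-14; 21 adjusted over the list alone), such as RPA135 (3.50-fold), NSR1 (2.90-fold), SSF1 (2.85-fold) and RRP12 (2.78-fold). FKH1 itself was lower in the authors' deposited table (2.54-fold, 20.9 to 8.23 FPKM, q = 0.000327), as were NDD1 (2.19-fold) and FHL1, a forkhead factor gene (1.81-fold), so that forkhead factors and partners had 1 higher and 3 lower of 9 (1 and 3 adjusted over the list alone). Of 27 replication initiation genes, 5 were lower and 1 higher in the authors' deposited table (adjusted p = 1 by Fisher's exact test; 5 and 1 adjusted over the list alone): among them DBF4, the regulator of the Cdc7 kinase (2.24-fold lower), the origin recognition genes ORC1 (2.18-fold lower) and ORC2 (2.10-fold lower), and TAH11, the Cdt1 gene of origin licensing (2.24-fold higher).

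Besides FKH2, the largest rises with Fkh2 OE in the authors' deposited table were an entry joining AQY2, an aquaporin gene, with YLL053C (7.03-fold), HBN1 (6.63-fold), SHC1 (4.58-fold), IMD4, a GTP synthesis gene (3.93-fold), RSA4, a ribosome assembly gene (3.86-fold), the cysteine transporter gene YCT1 (3.67-fold), RCK1 (3.55-fold), KTR5 (3.55-fold) and YDL062W (3.54-fold). The largest falls in the authors' deposited table were YLR112W (7.82-fold), SPG1 (6.39-fold), MDJ2 (6.33-fold), YML089C (5.83-fold), CSN9 (5.76-fold), SHE1 (5.23-fold), YBR285W (4.98-fold), the vacuolar fusion gene VAM7 (4.92-fold), CSE4, encoding the centromeric histone (4.64-fold, 112 to 24.1 FPKM), and the autophagy gene ATG14 (4.64-fold).

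The remaining lists reported here did not pass the adjusted Fisher test with Fkh2 OE. Pheromone response had 9 lower and 0 higher of 22 in the authors' deposited table (adjusted p = 0.141 by Fisher's exact test; 9 adjusted over the list alone), including FIG1 (2.23-fold), STE12 (2.00-fold), ASG7 (1.98-fold) and PRM3 (1.64-fold). Histones had 4 lower and 1 higher of 9 in the authors' deposited table (5 and 1 adjusted over the list alone), with HHO1 (3.80-fold), HHT2 (2.27-fold) and HTA1 (1.84-fold) lower and HHF1 (1.82-fold) higher. Stress genes had 6 lower and 1 higher of 19 in the authors' deposited table (6 and 1 adjusted over the list alone), with DDR2 (4.61-fold), TSL1 (3.92-fold), an entry joining GLK1 with YCL042W (2.75-fold) and SOL4 (2.16-fold) lower. The CLB2 cluster had 3 higher and 6 lower of 24 in the authors' deposited table (3 and 6 adjusted over the list alone), with CHS2 higher (2.28-fold) and BUD8 (2.03-fold), MOB1 (1.96-fold) and MYO1 (1.84-fold) lower. G1/S genes had 5 higher and 3 lower of 34 in the authors' deposited table (5 and 1 adjusted over the list alone), with POL1 (2.77-fold), POL2 (2.18-fold) and SMC3 (1.52-fold) higher and SWE1 (1.71-fold) lower.

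Methionine genes had 6 higher and 0 lower of 17 with Fkh2 OE in the authors' deposited table (6 and 1 adjusted over the list alone), including CYS3 (3.43-fold), MET17 (2.09-fold), MET10 (2.05-fold) and MMP1 (1.95-fold). Iron genes had 5 higher of 12 in the authors' deposited table (5 adjusted over the list alone), including SIT1 (2.69-fold), FET3 (2.61-fold), FTR1 (2.03-fold) and ARN2 (1.93-fold). Phosphate genes had 1 higher and 4 lower of 13 in the authors' deposited table (1 and 4 adjusted over the list alone), with PHO5 (2.43-fold), PHM8 (2.15-fold), SPL2 (1.79-fold) and VTC1 (1.60-fold) lower. For dNTP supply, RNR1 was higher (1.59-fold) and DIF1 (2.11-fold) and CRT10 (1.62-fold) lower of 10 in the authors' deposited table (1 and 2 adjusted over the list alone). Damage-induced genes had DDR2, DIN7 (1.74-fold) and RAD54 (1.45-fold) lower of 12 in the authors' deposited table (3 adjusted over the list alone). Ribosomal protein genes had 3 higher of 16, among them RPP0 (1.66-fold) and RPL32 (1.45-fold), in the authors' deposited table (1 adjusted over the list alone), and the α-cell list STE3 higher (2.48-fold) of 3 (1 adjusted over the list alone). Of 177 subtelomeric genes, 15 were higher and 12 lower in the authors' deposited table (12 and 11 adjusted over the list alone), among them LYS1 (2.42-fold) and ADH6 (2.04-fold) higher and MNT2 (2.09-fold) and an entry joining FDH2 with YPL276W (2.39-fold) lower. No call was made among 9 galactose, 4 flocculation and 7 mitochondrially encoded genes in the authors' deposited table (0 adjusted over the list alone).

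**Figure D4:**
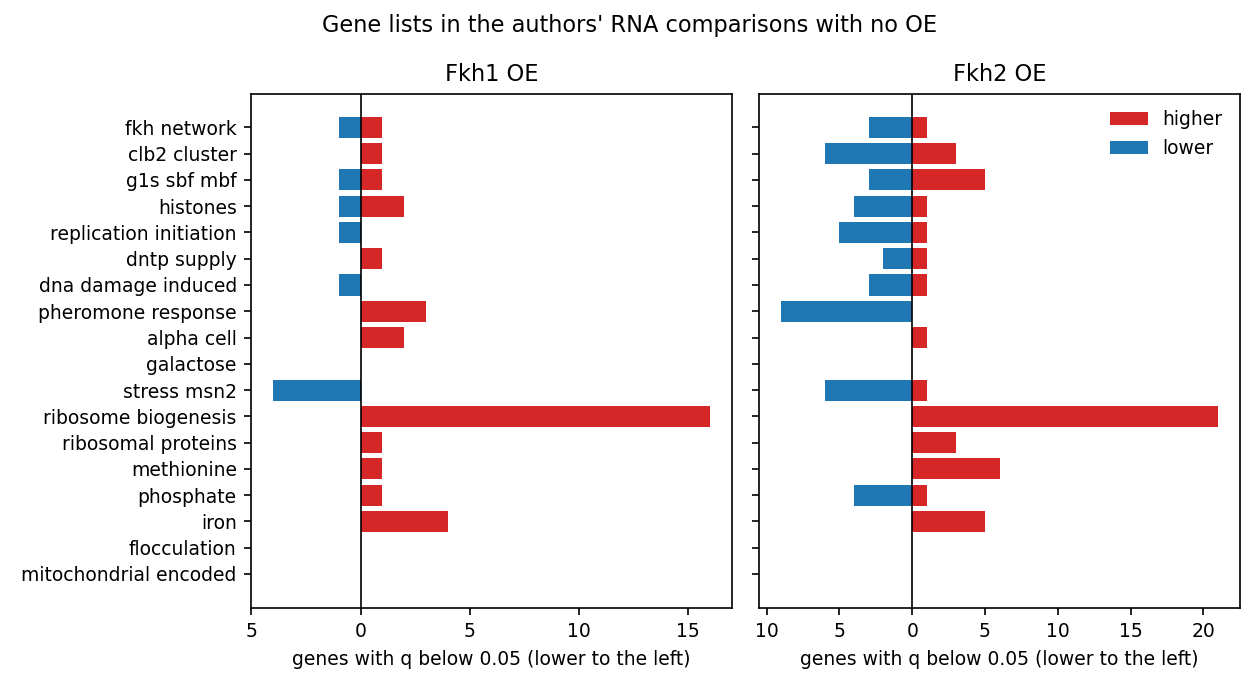
Number of genes with an authors' q below 0.05 in each fixed list reported here but the subtelomeric one, higher to the right (red) and lower to the left (blue) on a linear axis, for Fkh1 OE (left panel) and Fkh2 OE (right panel) over no OE in G1. Ribosome biogenesis has the longest bars, 16 and 21 genes higher of 24.

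Directly compared, 451 genes were higher and 727 lower in Fkh2 OE than in Fkh1 OE of 6227 tested in the authors' deposited table. FKH2 was 167-fold higher and FKH1 177-fold lower there in the authors' deposited table. Pheromone genes were called lower with Fkh2 OE more often than other genes: 11 of 22 were lower, 1 higher and the other 10 not called in the authors' deposited table (Fisher's exact test, adjusted p = 0.000213; 14 and 1 adjusted over the list alone), such as the a-factor genes MFA2 (4.75-fold) and MFA1 (2.67-fold), FIG1 (2.58-fold) and ASG7 (2.28-fold). Phosphate genes had 6 lower and 0 higher of 13 in the authors' deposited table (adjusted p = 0.0275 by Fisher's exact test; 6 adjusted over the list alone), with PHO5 (2.48-fold), PHO11 (2.44-fold, a gene with a near-identical copy), SPL2 (2.12-fold) and PHM8 (1.87-fold). Ribosome biogenesis had 13 higher and 0 lower of 24 in the authors' deposited table (adjusted p = 6.09e-08 by Fisher's exact test; 15 adjusted over the list alone), including YTM1 (1.83-fold), GAR1 (1.77-fold), RPA135 (1.65-fold) and NUG1 (1.64-fold).

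Other lists reported here did not pass the adjusted Fisher test between both strains. Histones had 4 lower of 9 in the authors' deposited table (4 adjusted over the list alone): HTA1 (2.27-fold), HHT2 (1.83-fold), HTB1 (1.76-fold) and HHO1 (1.62-fold). Replication initiation had 2 higher and 5 lower of 27 in the authors' deposited table (2 and 5 adjusted over the list alone), with TAH11 higher (1.84-fold) and DBF4 (2.25-fold), ORC1 (1.79-fold) and ORC2 (1.54-fold) lower. The CLB2 cluster had 3 higher and 5 lower of 24 in the authors' deposited table (3 and 5 adjusted over the list alone), with BUD8 (2.28-fold), MOB1 (1.79-fold), IQG1 (1.67-fold) and BUD3 (1.63-fold) lower. Forkhead factors and partners had 2 higher and 2 lower of 9 in the authors' deposited table (2 and 2 adjusted over the list alone), YOX1 higher (1.88-fold) and FHL1 lower (1.75-fold) besides FKH2 and FKH1. G1/S genes had 3 higher and 1 lower of 34 in the authors' deposited table (3 and 0 adjusted over the list alone), with POL1 (2.06-fold), YOX1 and POL2 (1.57-fold) higher and SMC1 lower (1.46-fold).

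Between both strains, stress genes had 3 higher and 4 lower of 19 in the authors' deposited table (3 and 4 adjusted over the list alone), with SSA4 (1.89-fold) and CTT1 (1.67-fold) higher and DDR2 (2.77-fold) and TSL1 (1.72-fold) lower. Methionine genes had 4 higher and 3 lower of 17 in the authors' deposited table (4 and 3 adjusted over the list alone), with CYS3 (2.60-fold), MMP1 (1.83-fold) and MET10 (1.81-fold) higher and MUP1 (1.77-fold) lower. Single calls in the authors' deposited table were SAG1 lower (1.80-fold) of 4 α-cell genes (1 adjusted over the list alone), DDR2 lower of 13 damage-induced genes (1), RPS15 higher (1583 to 2373 FPKM) of 16 ribosomal protein genes (0), FLO5 lower (1.54-fold) of 4 flocculation genes (2), and OLI1 higher (1.58-fold) of 7 mitochondrially encoded genes (3). Of 179 subtelomeric genes, 11 were higher and 14 lower in the authors' deposited table (8 and 8 adjusted over the list alone), among them MMP1, LYS1 (1.83-fold) and GTT1 (1.67-fold) higher and MNT2 (1.69-fold) lower. No call was made among 11 dNTP supply, 9 galactose and 12 iron genes in the authors' deposited table (0 adjusted over the list alone).

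The responses to both factors overlapped in RNA as well. Of 6161 genes tested in both comparisons with no OE in the authors' deposited table, 246 were higher in both, where independent lists would share 47.6, 289 were lower in both (57.5), and 5 were called in opposite directions. Across 6122 genes the log2 folds had r = 0.642 and rho = 0.644, with a covariance of 0.199. The shared control libraries alone gave a simulated r of 0.501, with equal noise assumed in each group. The controls could not be split, so how much of the excess comes from them is not known, and genes are not independent replicates.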

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

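In this part, the tests on early origins with Fkh2 OE and on URA3 were chosen only after the results were seen, as was the split of chromosome-end origins at 5 kb, while both other tests on chromosome ends were chosen before.

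Of 14 values of signal outside the nuclear origins, 6 were above the control column and 8 below it, none with a known spread. Mitochondrial DNA, which replicates outside S phase control, stood at 1.19 times control with Fkh1 OE in HU, at 1.03 times with Fkh2 OE in HU and at 1.07 times with Fkh1 OE in the pulse to 35 min. The ribosomal DNA array, which few bins covered, stood at 1.11 times control in the pulse to 35 min (48 bins), at 1.95 times in the double mutant with Fkh1 OE (49 bins) and at 2.93 times with RNR3 OE (58 bins). Below control, the array stood at 0.520 times with Fkh1 OE and 0.567 times with Fkh2 OE in HU (61 bins), and at 0.861 and 0.878 times in the pulses to 45 and 55 min. Mitochondrial DNA was at 0.909 and 0.784 times in those pulses, at 0.983 times in the double mutant with Fkh1 OE and at 0.922 times with RNR3 OE.

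Early origins had less signal with Fkh2 OE in HU, with a median fold of 0.540 in the early tercile. A lower scale of the whole column was argued against by background windows at 1.05 times control. Lower BrdU uptake or fewer replicating cells as the sole cause would raise no origin. Of the late tercile of origins called in the control column of the time course to 35 min, 21.9% were past 2-fold up, which argued against it. The 0.564% of background windows past 2-fold up is a weak comparator, since peaks called with the OE columns were kept out of them by construction. Also, 30 late origins of at least 3 times background in the HU control had a median fold of 0.929. Whether a fixed amount of BrdU moved from early to late origins stays open, because the scale of amount between columns is not known: the sum over origin windows was 0.608 times control as deposited and 0.936 times when scaled to the total. Combinations stay open too, as does an effect of Fkh2 OE itself, which was not tested.

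Signal inside URA3 (chromosome V 116167 to 116970) was 66.9 times its flanks in no OE, 17.5 times in Fkh1 OE and 3.12 times in Fkh2 OE in HU. A chromosomal origin at URA3 was argued against by the flanks in no OE, at 0.887 times background. Plasmid DNA, since cells were selected for a plasmid without uracil, stays open: the region between GAL1 and GAL10, which galactose-promoter plasmids share, also stood above its flanks in no OE and Fkh1 OE, at 6.84 and 1.95 times, but in the pulse to 35 min, where URA3 stood at 23.5 and 6.73 times, it was at 1.47 and 1.35 times where the mix of the HU no OE column would give 2.21 and 1.296. In the Fkh2 OE column that region was at 0.924 times its flanks where this mix would give 1.19, a gap too small to decide, and in the double mutant's table the bins inside URA3 were missing. The overexpressed genes showed no excess like that of URA3. In Fkh1 OE in HU, signal inside FKH1 was 0.0121 and in its flanks 0.0511, where URA3 had 0.0780 and 0.00446. In Fkh2 OE, FKH2 was at 0.810 times its flanks, beside 1.07 times in no OE. These values go against a plasmid with equal signal over URA3 and the overexpressed gene, while the GAL1-GAL10 region in no OE and Fkh1 OE goes with plasmid DNA. Whether the mix differed between experiments is not known, so plasmid DNA and other sources cannot be told apart, and no biological explanation other than a chromosomal origin was tested.

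Origins near chromosome ends stayed near control with Fkh1 OE in HU (median fold 1.05 over 25 origins). Signal too close to background was argued against, since 20 such origins of at least 3 times background had a median fold of 0.998, at percentile 0 of matched lists. Reads shared between near-identical ends stay open: the 8 origins further than 10 kb from the end had a median fold of 2.48, at percentile 47.25, too few origins to decide, while the median without the 10 origins within 5 kb was still 1.08 and that of the 7 origins at 5 to 10 kb was 0.932. An effect of Fkh1 OE that falls off with distance from the end would give the same values, stays open and was not tested. In the double mutant with Fkh1 OE, origins near chromosome ends stood above matched lists instead, at a median fold of 1.57 (percentile 99.97).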

How the results depend on the processing

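In this part, the tests chosen only after the results were seen were background subtraction, peaks of at least 10 times background, scaling to mitochondrial DNA, leaving out chromosome ends and URA3, the 1.5-fold rule, origins that pass in a control column alone, strong origins for the width, and the totals of the time course. No paired analysis was possible because the columns carry no replicate numbers and each group has 1 combined column. For the same reason, and because Input and counts were not used here, these alternatives, chosen beforehand, were not run: TMM, the Input count of the window as offset, DESeq2 and its size factors, fits of only the groups compared, leaving out each replicate, all annotated origins, estimated correlations of sets, and pseudocounts and filters of FPKM. Of 84 alternative values of median folds, 69 moved, 6 reversed and 9 stayed. Of 623 of named origins, 412 moved, 0 reversed while called and 211 stayed. Of 330 others, 146 moved, 18 reversed and 166 stayed. Part of those that stayed could not change. The 1.5-fold rule does not alter a median fold, and leaving out origins does not alter the fold of an origin that is kept. Scaling to the total does not alter Pearson's r. No spread is known for the values of single columns, so any shift of a fold, ratio or correlation that showed after rounding was counted as moved. Counts were held to have stayed when they changed by no more than 1.5 times. Depth could not be judged. Where a cause is not named below, the cause was not tested.

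With scaling to the IP total, which by construction divides each fold by that of the totals, Fkh1 OE in HU had 9 origins lower, and Fkh2 OE had 16 lower and a median fold of 1.49, reversed. Fkh2 OE against Fkh1 OE had 15 higher and 38 lower. The pulse to 35 min had 84 higher and 15 lower, and that to 45 min 25 higher and 4 lower with a median fold of 0.892, reversed. The effect at 55 against 35 min was smaller at 99 origins and larger at 18. The double mutant's median fold was 1.14, reversed, and RNR3 OE had 6 higher.

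Class medians under the same scaling were as follows, with reversed directions named. For Fkh1 OE in HU they were 0.884 (early, reversed), 3.98 (late), 0.889 (centromere, reversed) and 0.757 (telomere, reversed). For Fkh2 OE they were 0.828 (early), 2.73 (late), 0.924 (centromere) and 1.63 (telomere), and against Fkh1 OE 0.868 (early), 0.883 (late), 1.03 (centromere, reversed) and 1.71 (telomere, reversed). At 35 min they were 0.702 (early, reversed), 2.22 (late), 0.772 (centromere, reversed) and 0.537 (telomere, reversed). At 45 min they were 0.743 (early, reversed), 1.34 (late), 0.759 (centromere, reversed) and 0.640 (telomere), and at 55 min 0.742, 0.828, 0.752 and 0.907. In the double mutant they were 2.69, 0.696, 0.912 and 2.38, and for RNR3 OE 1.3003 (early), 0.928 (late, reversed), 1.27 (centromere) and 0.969 (telomere, reversed).

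Scaling to mitochondrial DNA gave RNR3 OE 35 higher, the pulse to 55 min a median fold of 1.01, reversed, and 7 origins with a larger effect at 55 min. It moved the median log2 fold of Fkh1 OE in HU from 0.95 to 0.70, of Fkh2 OE against Fkh1 OE from -1.29 to -1.09, of the pulses to 45 and 55 min from 0.28 to 0.42 and from -0.33 to 0.02, and of RNR3 OE from 0.40 to 0.51. Windows of 1 kb gave a median fold of 1.01 for Fkh2 OE in HU, reversed, and 1 and 2 origins lower at 35 and 45 min. Windows of 5 kb gave RNR3 OE 47 higher.

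Background subtraction gave 9 lower for Fkh1 OE in HU, 1 higher for Fkh2 OE against Fkh1 OE, 5 and 6 lower at 35 and 45 min, 3 higher and 106 lower at 55 min, 118 with a smaller effect at 55 min, and 208 higher and 8 lower for RNR3 OE. Peaks of at least 10 times background, which by construction are fewer, gave 58 higher for Fkh1 OE in HU, 23 higher for Fkh2 OE, 132 lower for Fkh2 OE against Fkh1 OE, 62, 8 and 0 higher in the 3 pulses, 106 smaller and 0 larger effects at 55 min, 31 lower and a median fold of 1.44, reversed, in the double mutant, and 3 higher for RNR3 OE. The 1.5-fold rule, which by construction calls more, gave 9 lower for Fkh1 OE and 111 lower for Fkh2 OE in HU, 4 lower at 35 min, 115 higher and 2 lower at 45 min, 10 higher and 16 lower at 55 min, 7 larger effects at 55 min, and 109 higher for RNR3 OE.

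Without chromosome ends and URA3, by construction with fewer origins, Fkh1 OE in HU had 0 lower, the pulse to 55 min 3 higher, and 1 effect was larger at 55 min. Class medians were then 1.25 (early), 5.59 (late) and 1.08 (telomere) for Fkh1 OE in HU, 1.79 (late) and 1.07 (telomere) for Fkh2 OE, 0.399 (early) and 0.410 (late) for Fkh2 OE against Fkh1 OE, 1.499 (early), 4.90 (late) and 1.40 (telomere) at 35 min, 1.83 (late) at 45 min, 0.7496 (early), 0.843 (late) and 0.847 (telomere) at 55 min, 1.76 (early), 0.418 (late) and 1.36 (telomere) in the double mutant, and 1.15 (telomere) for RNR3 OE.

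Origins were called on the mean of all HU columns, which by construction favours rises, and a minimum in the control column favours falls. With at least 1.5 times background in the HU no OE column, 37 origins were higher with Fkh2 OE and 28 in the pulse to 45 min, and the late tercile had a median fold of 2.00 (Fkh1 OE in HU), 1.16 (Fkh2 OE), 2.56, 1.51 and 0.824 (the 3 pulses). With at least 3 times, 65 were higher with Fkh1 OE in HU, 13 with Fkh2 OE, and 76, 8 and 3 in the 3 pulses, and the late medians were 1.36, 0.929 (reversed), 1.96, 1.18 and 0.821. Over origins called in the time course control to 35 min, 79 were higher with Fkh1 OE and 25 with Fkh2 OE in HU, with medians of 1.16 and 0.497 (early) and 1.65 and 1.08 (late).

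The ratio of the total between Fkh1 OE and no OE in HU was 1.36 from background and 1.52 from origin windows, and for Fkh2 OE 0.652 over all bins, 1.05 from background, reversed, and 0.608 from origin windows. At 35 min it was 2.12 over all bins, 1.88 from background and 1.86 from origin windows, at 45 min 2.60 and 1.21 from the latter pair, and at 55 min 1.22 and 0.838, the last reversed. The ratio of the flank share between OE and its control was 0.473 (Fkh1 OE in HU), 0.748 (Fkh2 OE), 0.745 (double mutant) and 0.985 (RNR3 OE), and in that order 0.455, 0.841, 0.885 and 0.847 at 6 to 9 kb, 0.359, 0.433, 0.590 and 1.42 (reversed) after background subtraction, and 0.789, 1.16 (reversed), 0.430 and 2.30 (reversed) over strong origins. The swapped site's fold was 2.22 in flanks 3 to 6 kb away.

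Over origins with a call in either comparison, which by construction leaves out small folds, Pearson's r of Fkh1 OE in HU was 0.911 with Fkh2 OE in HU, 0.772, 0.280 and -0.25 with the 3 pulses, -0.45 with the double mutant and -0.44 with RNR3 OE, and that of Fkh2 OE in HU was 0.863 with the pulse to 35 min and -0.60 with the double mutant. In the authors' deposited table, q below 0.01, by construction stricter, gave 154 genes higher and 168 lower with Fkh1 OE, 566 higher with Fkh2 OE, and 186 higher and 441 lower between both. A 2-fold minimum on the folds of the authors' deposited table gave 24 and 59, 222 and 438, and 34 and 149.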

Other observations

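In this part, the 5 genes below were picked only after the results were seen, while the tests of both hypotheses were chosen before.

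Genes called in opposite directions by the 2 factors in G1 numbered 5 in the authors' deposited table. FKH1 itself was 69.6-fold higher with Fkh1 OE and at 0.393 times control with Fkh2 OE. The a-factor gene MFA2 was at 2.83 and 0.596 times control in the authors' deposited table, and the cell wall gene SCW4 at 1.54 (q = 0.00718) and 0.426 times. HXT7, a hexose transporter gene with a near-identical copy, was at 1.49 (q = 0.0165) and 0.616 times (q = 0.00260) in the authors' deposited table, and YCR024C-B at 1.44 (q = 0.0340) and 0.688 times (q = 0.0317).

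A first hypothesis was that origins change where transcription of the nearest gene changes. Over 279 origins, the log2 fold of Fkh1 OE in HU was set against that of the nearest gene's RNA in the authors' deposited table. Spearman's rho was 0.0281 (permutation p = 0.641, 2-sided, 100000 permutations) and Pearson's r 0.0565. These values argued against a link of 1 direction. A link in which transcription raises some origins and lowers others would not show in them. Few genes changed much, 24 higher and 59 lower by at least 2-fold, which limits the test. Origins are not independent replicates, and RNA was measured in G1.

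A second hypothesis was that Fkh1 OE brings the ranking of origins in the double mutant nearer to that of cells with both genes. The rank correlation with the no OE column of the RNR3 table was 0.390 without and 0.825 with Fkh1 OE, a difference of 0.435, as the hypothesis predicts. With the no OE column of the HU table it was 0.406 and 0.885, a difference of 0.479. The tables were normalised separately, so ranks alone were compared, and 1 column per group leaves the difference without an error.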
